A study of Homo sapiens with 6 samples.

How the data were processed

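Gene expression was measured on Affymetrix whole-transcript arrays in 3 derivatives of HEK293, a human embryonic kidney cell line. The derivatives carry an empty vector (vector), an inducible wild-type APE1 (wtAPE1) or an inducible fusion of ubiquitin to APE1 (ubAPE1). Each line was sampled without doxycycline and after 16 h with doxycycline at 2 µg per ml, the drug that switches on the transgene in this tet-on system, and all were grown with puromycin at 1 µg per ml. The 6 groups hold 1 deposited column each, and per the labels each column is the mean of 3 biological replicates averaged by the authors. The spread between those replicates is not in the values used here.

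The deposited values are log2 expression levels per array row (transcript cluster), as the authors made them from the probes. The log2 scale was read from the values themselves, since the summarisation, background correction, normalization and any row filter are not given in the sources used here. The submitters' processing notes name genome build hg 18, and the gene table used here is for assembly GRCh38.p14, so no coordinates are given. The table holds 15492 rows. Of these, 12616 have 1 gene symbol in the platform's annotation, 2031 have several and 845 have none, and no gene is named from a row with several. The gene IDs of 12602 of the 1-symbol rows were found in the gene table, and 0 symbols needed updating. No pair of columns was identical.

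Rows with a mean over the 6 samples at or above the 25th percentile of all row means (5.03 log2) were kept, which left 11619 rows. Of these, 9653 had 1 symbol, for 9569 genes. Differences between samples were taken on the log2 scale. Where the columns are shifted against each other, a difference is given relative to the median row, which means that the median difference over the kept rows was subtracted.

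Comparisons between single columns were described by size, with rows at least 1.5-fold higher or lower counted, and carry no test. Tests were made with limma (version 3.58.1, R 4.3.3), lmFit and eBayes, with Benjamini-Hochberg adjustment over all kept rows and a threshold of 0.05. The additive fit had cell line and doxycycline as terms (2 residual degrees of freedom, 6.28 prior) and gave the common doxycycline effect and the differences between lines. A fit with a further term for induced APE1 (1 residual degree of freedom, 30.3 prior) gave the effect of induction beyond doxycycline. In these fits the cell lines, or the doxycycline states of a line, stand in for replicates, so the p-values measure evenness across them. The median residual SD was 0.151 log2. Adjusted p-values belong to the differences as deposited, also where the size printed beside them is relative to the median row.

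For 25 gene lists fixed before the data were examined, the median difference over the measured genes (for each gene, its row with the highest mean) was placed among 10000 random lists of the same size matched on mean expression in 10 bins. The percentile is a description of these samples, not a test. A list was called apart at or below the 2.5th or at or above the 97.5th percentile, and 23 lists had the 3 measured genes needed. The common doxycycline effect was also tested with limma's camera, with a preset correlation of 0.01 and with an estimated one. Named genes followed a rule that was also fixed beforehand. It takes, among others, APEX1 and UBB, and the 10 rows with the largest rise and the 10 with the largest fall among 1-symbol rows past the threshold of a test or, without a test, among kept 1-symbol rows. Where fewer than 5 rows passed in a direction, it takes the 10 largest changes that went the same way in every line (for induction, in both APE1 lines), as values only. From each list it takes the members past the threshold or past 1.5-fold, or else the 2 members with the largest change. Some named genes are left out for length. For 84 genes with several kept rows, a value belongs to the row chosen by that rule, and disagreement of the other row is stated.

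Alternatives were no row filter, a filter at the 50th percentile of row means, quantile normalization, centring each column on its median, raising values under the 10th percentile (4.09 log2) to it, an intensity trend with robust eBayes, no cell line term, leaving out each line, 1 row per gene, the additive fit's spread for the induction term, a 2-fold size rule, all rows of each listed gene and unmatched random lists. The alternative with a pseudocount, meant for linear values, was not run because the values are log2. Chosen after seeing the data were the removal of a genomic length trend (median within 20 length bins), and camera with each line left out or under the other filters and normalizations.

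The fits were tested on simulated data with known changes on 11619 rows and noise drawn independently for each row. Noise shared across rows, such as a length trend, is not covered by these figures. For the common doxycycline effect, 77% of rows changed 2-fold and 5% of rows changed 1.5-fold were recovered, with 4 false calls among 86. For induction beyond doxycycline 0% were recovered at either size, and for wtAPE1 minus vector 2% at 2-fold and 0% at 1.5-fold. Of 100 unchanged simulated lists, 7% lay outside the percentile limits, and all 20 lists shifted by 0.2 log2 lay above the upper one. These lists were random genes with the response shuffled over rows, so their members did not move together. Lists of genes that do can stray further, and the 7% is not their rate. Reading and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.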

Results

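The data are 6 averaged expression profiles of HEK293 derivatives with an empty vector, inducible wild-type APE1 or an inducible ubiquitin-APE1 fusion, each with and without doxycycline. APE1, the product of APEX1, is the main endonuclease for abasic sites in base excision repair. The design asks what the wild-type protein or the fusion changes beyond doxycycline itself. The columns had medians of 6.28 (vector) and 6.07 (wtAPE1) and 6.21 (ubAPE1) log2 without doxycycline, and 6.23, 6.12 and 6.07 with it. Each value is 1 averaged column per group, and this number limits the precision throughout.

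APEX1 was measured first, as a check of the labels. Its level was 9.54 log2 without and 9.66 with doxycycline in the vector line, 9.50 and 10.67 in the wtAPE1 line, and 9.82 and 10.58 in the ubAPE1 line. Relative to the median row, the APEX1 response was 0.17, 1.102 and 0.88 log2, or 1.12-fold, 2.15-fold and 1.84-fold. It ranked 2 of 11619 rows from the top in the wtAPE1 line and 12 in the ubAPE1 line, against 1961 in the vector line. Without doxycycline, APEX1 was higher than in the vector line by 0.32 log2 in the ubAPE1 line relative to the median row (0.29 as deposited), and in the wtAPE1 line the difference was 0.17 relative to the median row but -0.04 as deposited. UBB, which encodes ubiquitin, lay between 12.05 and 12.26 log2 in all 6 samples.

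**Figure D1:**
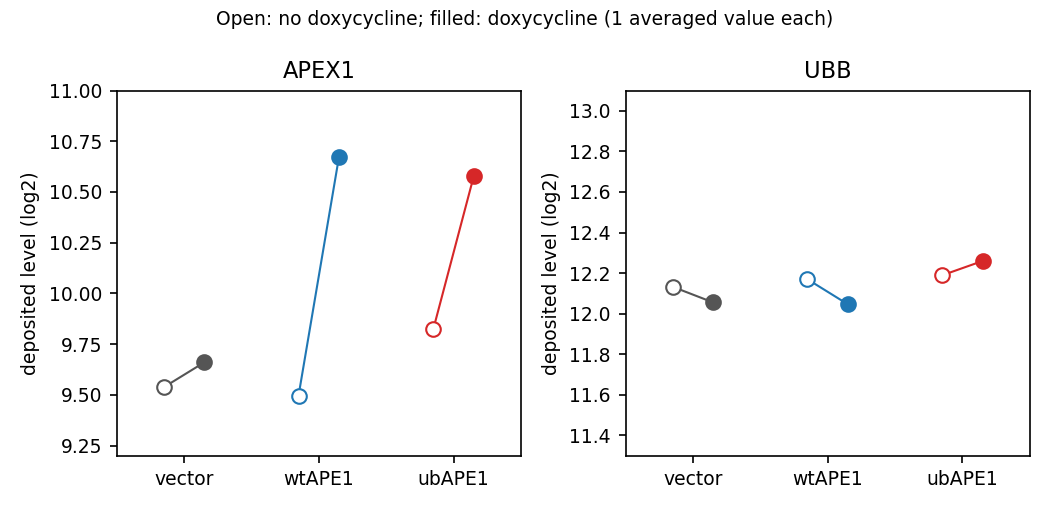
Deposited log2 levels of APEX1 (left) and UBB (right) by cell line, with open points without and filled points with doxycycline, each point 1 averaged value. APEX1 went from 9.50 to 10.67 in the wtAPE1 line and from 9.82 to 10.58 in the ubAPE1 line, against 9.54 to 9.66 in the vector line, and UBB lay between 12.05 and 12.26.

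The response to doxycycline was then described within each line. In the vector line, the replication-dependent histones, which package new DNA in S phase, had a median response of -0.35 log2 relative to the median row (percentile 0 among random lists), with 18 of 21 measured genes below it and H2AC21 at -0.59. Cytosolic ribosomal proteins also lay low (-0.26, percentile 0), with RPL11 at -0.61 and RPL18 at -0.60. Among single genes, the lipoxygenase ALOX12 (1.02) and the homeobox gene HOXC11 (0.93) were among the highest, and the depalmitoylase LYPLA1 (-1.27) and the histone gene H2BC4 (-1.05) among the lowest. Mitosis genes had a median of -0.11 (percentile 1.8), with CDK1, the mitotic kinase, at -0.46. ATF4 and integrated stress response targets had a median of 0.09 (percentile 98.3), with MTHFD2, a mitochondrial folate enzyme, at 0.60.

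In the wtAPE1 line the histone median was -0.37 (percentile 0), with H4C1 at -1.23 and H4C4 at -0.87. Nuclear genes of the respiratory chain lay at -0.15 (percentile 0), with NDUFA1 of complex I at -0.68 and COX5B of complex IV at -0.59. COX7A2 (-1.13) and UQCRQ (-0.93), which encode further respiratory chain subunits, were among the 10 lowest rows. Mitosis genes lay at 0.24 (percentile 99.9), with 14 of 18 above the median row, NUSAP1 at 0.49 and CDC20 at 0.48. Glycolysis genes lay at 0.23 (percentile 98.9), with PGK1 at 0.62, and mitochondrial ribosomal proteins at -0.06 (percentile 0.87), with MRPL12 at -0.29. After APEX1, the purine salvage enzyme PNP (0.95), the mitochondrial peroxiredoxin PRDX3 (0.78) and the chaperone HSPA8 (0.75) were among the highest.

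In the ubAPE1 line, mitosis genes lay at -0.23 (percentile 0.86), with HMMR at -0.95 and CENPF at -0.59. Epithelial and kidney tubule markers lay at 0.28 (percentile 98.5), with the tight junction gene CLDN3 at 0.69. The histone median was 0.02 (percentile 72.0). The ribosomal protein gene RPL41 (1.246) and the mitochondrial import gene TOMM7 (0.90) were among the highest rows. The cap-binding translation factor EIF4E (-1.23), the complex II subunit SDHC (-1.08) and SEPTIN7 (-1.06) were among the lowest. EIF4E was also among the 10 lowest in the wtAPE1 line, at -0.80.

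By the size rule, 23 rows were at least 1.5-fold higher and 100 lower in the vector line, 123 higher and 34 lower in the wtAPE1 line, and 43 higher and 996 lower in the ubAPE1 line. The median row moved by -0.05, 0.07 and -0.13 log2 in the 3 lines. Relative to it the counts were 40 higher and 70 lower, 59 and 49, and 141 and 443, and after quantile normalization 37 and 63, 54 and 64, and 134 and 372. The ubAPE1 response also went with gene length. Of 4 classes of genomic length, the shortest (520 rows) had a median ubAPE1 response of 0.24 and the longest (1695 rows) -0.15 relative to the median row, against -0.06 and 0.03 in the vector line. With that trend removed, the histone list lay at percentile 0.36 in the ubAPE1 line as well, and the mitosis list lay at 1.39, 99.9 and 0.06 in the 3 lines. Lists called above that came inside the limits were the ATF4 targets in the vector line (96.0), mitochondrial ribosomal proteins in the wtAPE1 line (3.71) and epithelial markers in the ubAPE1 line (95.9).

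**Figure D2:**
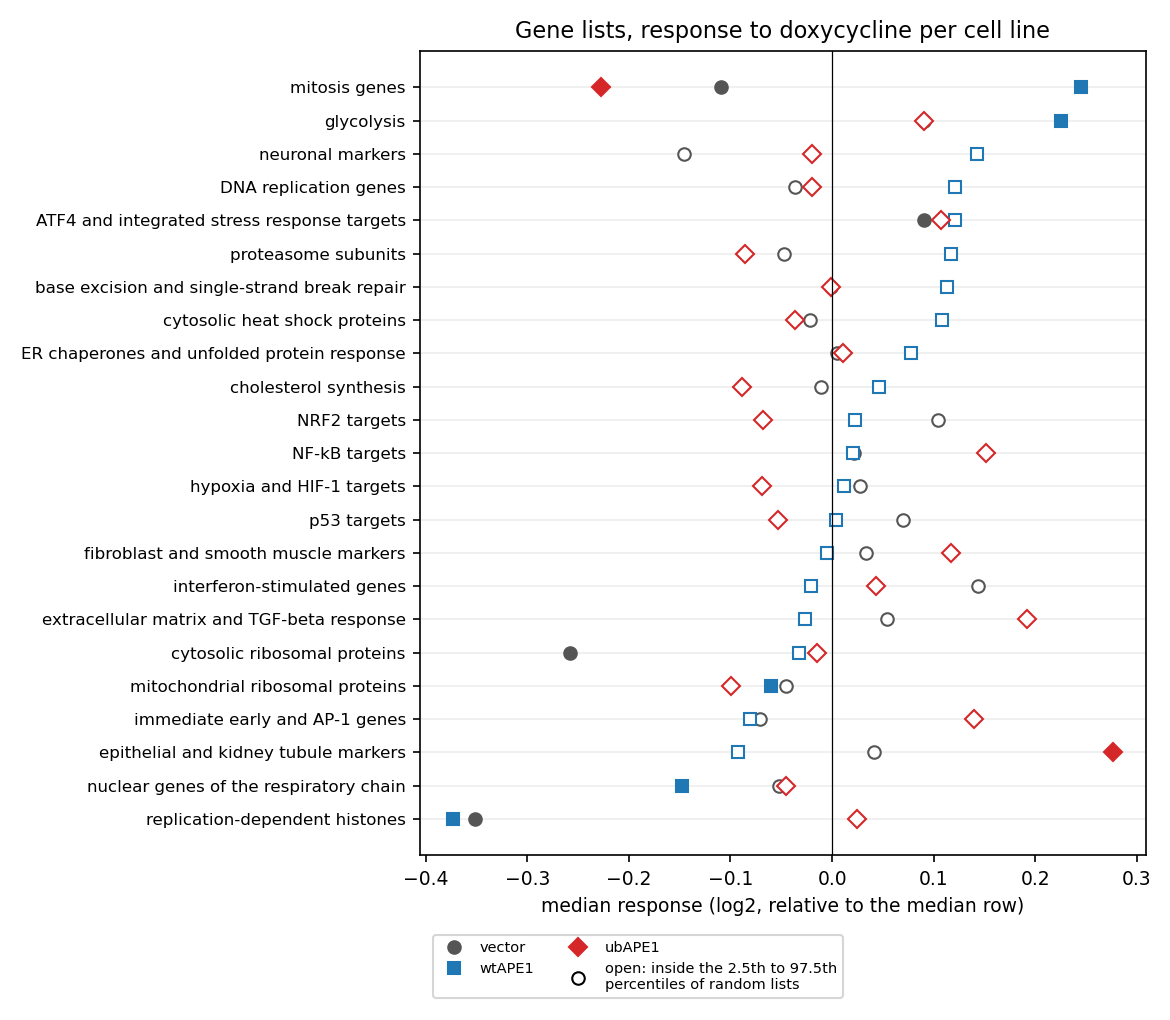
Median response to doxycycline (log2, relative to the median row) of each gene list with at least 3 measured genes, in the vector (circles), wtAPE1 (squares) and ubAPE1 (diamonds) lines, with filled symbols outside the percentile limits of matched random lists. The histone list lies at -0.35 and -0.37 in the vector and wtAPE1 lines and at 0.02 in the ubAPE1 line, and the mitosis list at -0.11, 0.24 and -0.23.

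Where the lists above lay inside the limits, the percentiles were 96.3 and 97.0 for the ATF4 targets (wtAPE1 and ubAPE1), 8.64 and 50.7 for cytosolic ribosomal proteins (the same lines), 10.5 and 35.6 for the respiratory chain (vector and ubAPE1), 89.6 and 90.2 for glycolysis and 13.3 and 17.9 for mitochondrial ribosomal proteins (the same lines), and 73.9 and 9.81 for epithelial markers (vector and wtAPE1). The other lists lay inside the percentile limits in all 3 responses. Base excision and single-strand break repair genes, the pathway of APE1, had medians of -0.00147, 0.11 and -0.00141 in the vector, wtAPE1 and ubAPE1 lines, with the glycosylase TDG at 0.43 in the wtAPE1 line and NEIL3 at -0.56 in the ubAPE1 line. Their percentiles were 52.2, 93.6 and 64.7. In the same order, the percentiles were 93.6, 54.7 and 29.8 for p53 targets, 94.5, 46.1 and 32.9 for NRF2 targets, 66.2, 66.8 and 88.8 for NF-kB targets and 4.17, 3.58 and 96.3 for immediate early and AP-1 genes. They were 73.2, 56.0 and 30.9 for hypoxia targets, 44.2, 62.1 and 30.9 for cholesterol synthesis, 12.5, 71.7 and 20.6 for proteasome subunits, and 19.1, 77.9 and 59.7 for DNA replication genes. Interferon-stimulated genes lay at 97.3, 53.6 and 48.6, endoplasmic reticulum chaperones at 45.4, 68.7 and 66.4, and cytosolic heat shock proteins at 34.1, 79.3 and 58.8. Extracellular matrix genes lay at 83.4, 33.7 and 97.47, neuronal markers at 7.51, 84.8 and 49.2, and fibroblast and smooth muscle markers at 63.0, 44.0 and 72.0. Of the mitochondrially encoded genes, ND5 and ND6 were measured, with responses of -0.57 and -0.35, 0.41 and -0.31, and -0.44 and -0.18. Of the blood cell markers, CD8A and CD68 were measured, at -0.14 and -0.08, -0.36 and -0.05, and 0.24 and 0.38.

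A doxycycline effect common to the 3 lines was tested next. The histone list was lower by limma's camera with the preset correlation (adjusted p = 7.32e-12) but not with an estimated one (adjusted p = 0.714), with 19 of 21 members below 0. As deposited, H4C4 (-0.60) and H4C1 (-0.59) were among the 10 lowest rows that moved the same way in every line, although relative to the median row H4C1 was at 0.02 in the ubAPE1 line. Glycolysis genes were higher (adjusted p = 1.07e-04, 13 of 14 members above 0), as were ATF4 and integrated stress response targets (adjusted p = 0.00726, 18 of 27), and nuclear genes of the respiratory chain were lower (adjusted p = 0.00480, 20 of 26). Like the histones, these 3 calls did not hold with an estimated correlation, with adjusted p = 0.714 for the respiratory chain and adjusted p = 0.926 for glycolysis and the ATF4 targets. That version of camera rests on the 2 residual degrees of freedom, so a list could hardly pass, and the loss does not decide on a call. For the respiratory chain the estimated correlation was -0.0056, below the preset 0.01, yet camera's unadjusted p went from 6.27e-04 to 0.0621. Of single rows, 0 passed in limma, and 194 had an unadjusted p under 0.05. Of rows that moved the same way in every line, NPHS1 (0.71) and APEX1 (0.68) were among the highest by mean over the lines. EIF4E (-0.74), COX7A2 (-0.74) and the glutaredoxin GLRX (-0.62) were among the lowest, and none of these passed. Such a mean need not be even over the lines. As deposited, APEX1 responded by 0.12 in the vector line, against 1.18 in the wtAPE1 and 0.75 in the ubAPE1 line. With the columns centred, 9 rows passed, 4 higher and 5 lower. Adjusted over the list alone, 2 histone genes were lower, against 0 adjusted over all rows, and no other list had a member past the threshold either way. Against random lists, the medians of cytosolic ribosomal proteins (percentile 2.21) and mitochondrial ribosomal proteins (1.37) also lay low, without a camera call.

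**Figure D3:**
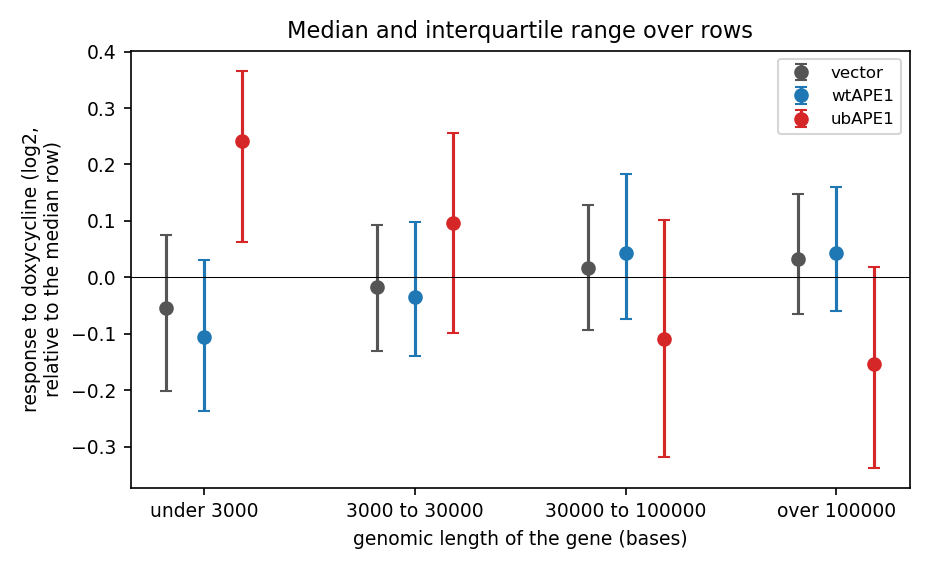
Response to doxycycline (log2, relative to the median row) by genomic length of the gene, as the median and interquartile range over rows in each cell line. The ubAPE1 medians run from 0.24 in the shortest class to -0.15 in the longest, and the wtAPE1 medians from -0.11 to 0.04.

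The responses of the lines were then set against each other, which is the comparison closest to the question of the design. Mitosis genes responded higher in the wtAPE1 line than in the vector line by a median of 0.37 log2 (percentile 99.99), and lower in the ubAPE1 line than in the wtAPE1 line (-0.55, percentile 0). Histones responded higher in the ubAPE1 line than in the vector line (0.31, percentile 99.99) and the wtAPE1 line (0.35, percentile 99.98), and lower in the wtAPE1 than in the vector line (-0.11, percentile 1.67). With the length trend removed, these 3 histone percentiles were 82.9, 81.0 and 5.205. Proteasome subunits responded higher in the wtAPE1 than in the vector line (0.22, percentile 98.1), with PSMB6 at 1.06. Cytosolic ribosomal proteins did so in the ubAPE1 line (0.27, percentile 99.0), and respiratory chain genes responded higher in the ubAPE1 than in the wtAPE1 line (0.21, percentile 99.96). Immediate early and AP-1 genes did as well (0.24, percentile 98.9). With the length trend removed, the proteasome, ribosomal, respiratory chain and immediate early percentiles were 96.5, 90.9, 96.6 and 54.0, inside the limits.

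Relative to the median row, the excess over the vector response was among the largest for FN1 in the wtAPE1 line (1.36), although its brighter row gave -0.03, and for WFS1 (1.38), RPL41 (1.33) and MYCN (1.22) in the ubAPE1 line. CHRM4 (-1.93) was lowest in the wtAPE1 line, and RWDD4 (-1.93) and the mitochondrial enzyme gene HIBCH (-1.49) were among the lowest in the ubAPE1 line. APEX1 exceeded the vector response by 0.94 and 0.69. Against the vector line, 630 rows were at least 1.5-fold higher and 81 lower in the wtAPE1 response, and 277 and 1412 in the ubAPE1 response. The ubAPE1 response against that of wtAPE1 gave 105 and 2360. The median row differed by 0.12, -0.06 and -0.22, and relative to it the counts were 297 and 177, 406 and 1132, and 532 and 890.

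As a test of induced APE1 over both APE1 lines, the limma fit called 0 rows, and 87 had an unadjusted p under 0.05. By the mean of both lines beyond the vector response, FN1 (1.19, with its brighter row at -0.25), WFS1 (1.15), PSMB6 (1.13) and RPL18 (1.06) were among the highest. RWDD4 (-1.32) and HIBCH (-1.14) were among the lowest. The same vector response is subtracted from both lines, so a like sign in both can come from it alone. Cytosolic ribosomal proteins had a median of 0.19 relative to the median row (percentile 97.54, or 91.6 with the length trend removed), and no list had a member past the threshold over all rows or adjusted over the list alone. As given above, the ribosomal list lay low in the vector response and inside the limits in the response of either APE1 line. In simulated data this fit recovered 0% of rows changed 2-fold, so the count of 0 does not bound effects of that size.

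Differences between the lines over both doxycycline states were the largest in the data. Relative to the median row, the actin-bundling gene LCP1 was higher than in the vector line by 3.45 ± 0.18 log2 (SE) in the wtAPE1 line (limma adjusted p = 2.69e-04) and by 3.69 ± 0.18 in the ubAPE1 line (adjusted p = 1.75e-04). The matrix protein gene SPARC (3.01 and 3.15) and the glutathione transferase GSTP1 (2.21 and 2.35) were also higher in both lines, as were the decoy receptor gene TNFRSF10D (1.54 and 1.65) and IRF8 (1.21 and 1.19). MAL2, a gene of apical transport in epithelia, was lower by the widest margin (-4.65 and -4.79, adjusted p = 2.51e-05 and 2.25e-05). The epithelial adhesion gene EPCAM (-3.01 and -2.98), the neuronal enolase ENO2 (-2.39 and -2.51), ETV5 (-2.24 and -2.09), a transcription factor downstream of growth factor signalling, and ANXA1 (-2.15 and -1.97) were lower in both.

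**Figure D4:**
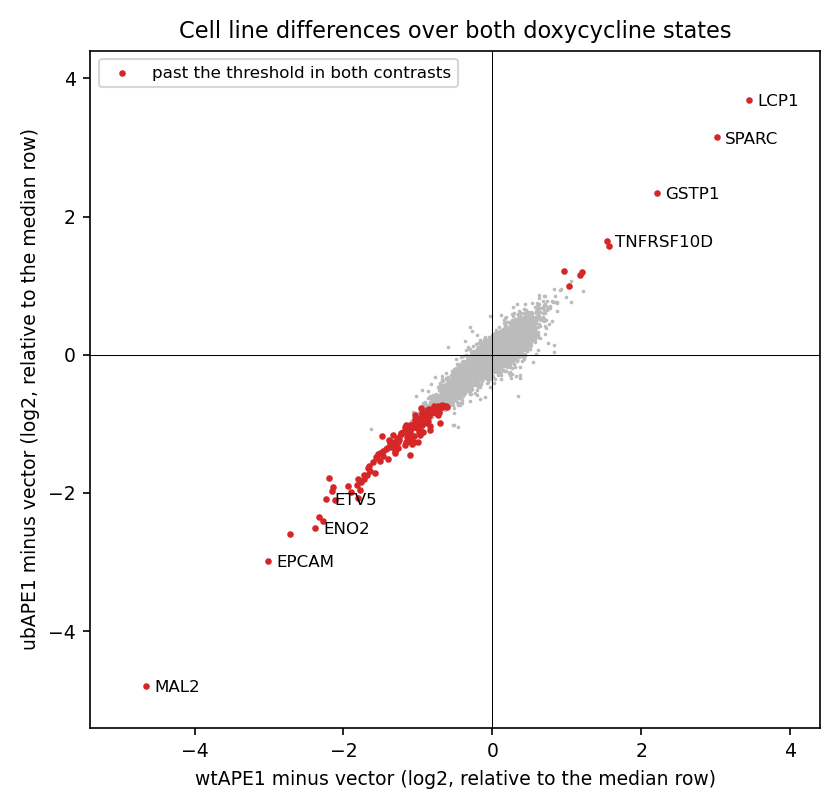
Difference of each kept row from the vector line over both doxycycline states (log2, relative to the median row), in the wtAPE1 line on the horizontal and the ubAPE1 line on the vertical axis, with rows past the limma threshold in both contrasts in red. LCP1 lies at 3.45 and 3.69 and MAL2 at -4.65 and -4.79.

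Among the lists, ATF4 and integrated stress response targets were lower in both lines. Of 27 measured genes, 10 were lower in the wtAPE1 and 7 in the ubAPE1 line over all rows, and 20 and 17 adjusted over the list alone. The glutathione degrader CHAC1 (-1.30 and -1.28), the cysteine-producing enzyme CTH (-1.14 and -1.11) and asparagine synthetase ASNS (-0.94 and -0.93) were lower in both. Their list medians were -0.49 and -0.47 (both percentile 0). Of 16 cholesterol synthesis genes, 2 were lower in the wtAPE1 and 0 in the ubAPE1 line (7 and 4 adjusted over the list alone), with HMGCS1 at -1.05 in the wtAPE1 line and list medians of -0.37 and -0.29 (both percentile 0). Of 16 hypoxia targets, LOX (-0.94 and -0.98) and BHLHE40 (-0.93 and -0.91) were lower in both lines, and 6 and 5 were lower adjusted over the list alone, with percentiles of 3.50 and 0.46. DUSP6, a feedback phosphatase of the ERK pathway, was the member of the immediate early and AP-1 list that was lower in both lines (-1.06 and -1.04), with 5 and 7 lower adjusted over the list alone and percentiles of 19.8 and 0.48.

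Extracellular matrix genes had medians of 0.35 and 0.34 (both percentile 100), of which SPARC passed over all rows and 3 in each line adjusted over the list alone. For p53 targets the medians were 0.20 and 0.16 (percentiles 99.3 and 99.8), with 0 members past the threshold over all rows and 1 higher in each line adjusted over the list alone. Of 10 epithelial and kidney tubule markers, EPCAM and KRT19 (-0.85 and -0.89) were lower in both lines and LRP2 (-0.77) in the wtAPE1 line, with 4 lower in each line adjusted over the list alone, and percentiles of 76.4 and 38.5. NEFL (-0.67) passed in the wtAPE1 line among 4 neuronal markers, of which 2 were lower in each line adjusted over the list alone. That list's percentiles were 0.95 and 1.53, and its shift turned sign without the row filter. ENO2 was the glycolysis gene that passed in both lines, H2AC8 (-1.18 and -1.04) the histone gene, and SDHA (-0.92), XBP1 (-0.68) and IFITM1 (1.22) passed in the wtAPE1 line among the respiratory chain, unfolded protein response and interferon lists. Adjusted over the list alone, 1 glycolysis gene, 1 histone gene and 1 respiratory chain gene were lower in each line, 2 unfolded protein response genes were lower in each, 1 interferon-stimulated gene was higher in each, 1 heat shock gene was higher in the wtAPE1 line and 1 blood cell marker was lower in the ubAPE1 line. Members of the other lists passed in neither contrast. Cytosolic ribosomal proteins had a higher median in the wtAPE1 line (0.13, percentile 98.0) and heat shock proteins in the ubAPE1 line (0.12, percentile 97.8).

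In limma, 12 rows were higher and 233 lower in the wtAPE1 line than in the vector line, and 10 higher and 152 lower in the ubAPE1 line. After quantile normalization these were 127 and 431, and 98 and 336, and with centred columns 188 and 468, and 126 and 413. The median row differed by -0.15 and -0.08. With the stricter row filter, 112 and 62 rows passed in all. Both contrasts share the vector samples. They shared 9 higher and 148 lower rows, against 0.0103 and 3.05 for independent lists. Simulations of unchanged lines against the same vector samples drew independent noise per row, without a length trend. They called means of only 0.31 and 0.34 rows per contrast. Their shared counts (means of 0.03 and 0.02) were therefore low by design and do not bear on the overlap of the rows called. The correlation across rows was 0.92, against 0.499 in those simulations, and the covariance 0.0821 against 0.0154. Between ubAPE1 and wtAPE1, 0 rows passed in limma, 47 had an unadjusted p under 0.05, and 1 row passed with centred columns. Proteasome subunits (percentile 99.8) and DNA replication genes (99.1) had higher medians in the ubAPE1 than in the wtAPE1 line, by 0.12 and 0.11 relative to the median row. Cytosolic ribosomal proteins (-0.08, percentile 0.08), histones (-0.06, percentile 0.32) and interferon-stimulated genes (-0.14, percentile 1.85) had lower ones. With the length trend removed, the DNA replication, histone and interferon percentiles here were 88.1, 29.4 and 16.8, and the neuronal percentile for ubAPE1 minus vector was 2.63. Each line is a single derivative, so the contrasts compare these lines and not transgenes.

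Without doxycycline the same genes led. LCP1 was higher than in the vector line by 3.35 log2 in the wtAPE1 line and 3.802 in the ubAPE1 line relative to the median row, SPARC by 2.95 and 3.19 and GSTP1 by 2.12 and 2.27, while MAL2 lay at -4.31 and -4.66 and EPCAM at -2.70 and -2.69. The secreted growth factor gene BMP2 was higher by 1.17 and 1.37. ATF4 and integrated stress response targets had medians of -0.59 and -0.55 (both percentile 0), with CHAC1 at -1.42 and -1.57. Mitosis genes lay at -0.26 in the wtAPE1 line (percentile 1.0) and were higher in the ubAPE1 than in the wtAPE1 line by 0.28 (percentile 99.5). Immediate early and AP-1 genes lay at -0.28 in the ubAPE1 line (percentile 0), with DUSP6 at -1.03. Extracellular matrix genes had medians of 0.41 and 0.20 in the wtAPE1 and ubAPE1 lines, p53 targets 0.25 and 0.28, cholesterol synthesis -0.33 and -0.16 and neuronal markers -0.60 and -0.43, the last of which turned sign without the row filter. Outside the limits in 1 line were interferon-stimulated genes (0.36) and proteasome subunits (-0.22) in the wtAPE1 line, and hypoxia targets (-0.21), epithelial markers (-0.17) and histones (-0.12) in the ubAPE1 line. Between ubAPE1 and wtAPE1, epithelial markers (-0.30), immediate early genes (-0.23), histones (-0.17), cytosolic ribosomal proteins (-0.16) and the respiratory chain (-0.09) had lower medians. In the wtAPE1 line, 52 rows were at least 1.5-fold higher and 1570 lower than in the vector line, in the ubAPE1 line 99 and 398, and the ubAPE1 line against the wtAPE1 line gave 748 and 24. The median row differed by -0.21, -0.04 and 0.17, and relative to it the counts were 228 and 597, 125 and 341, and 117 and 104. This difference for the wtAPE1 line also went with genomic length (Spearman rho -0.307 across 9645 rows, against 0.0502 for the ubAPE1 line and 0.399 for ubAPE1 against wtAPE1), as did the differences from the vector line over both states (-0.337 and -0.273). With the length trend removed, the ATF4 targets lay at percentile 0 and extracellular matrix genes at percentile 100 for wtAPE1 minus vector both without doxycycline and over both states. In the same setting, the percentiles were 88.1 for the interferon-stimulated genes and 3.79 for mitosis genes in the wtAPE1 line without doxycycline, and 65.1 for cytosolic ribosomal proteins in the wtAPE1 line over both states. For the ubAPE1 line without doxycycline the histone percentile was 6.405, and against the wtAPE1 line the percentiles were 74.5 for histones, 14.1 for immediate early genes, 13.24 for cytosolic ribosomal proteins and 8.65 for epithelial markers. The wtAPE1 sample without doxycycline correlated across rows with the ubAPE1 sample with it at 0.988 and with the ubAPE1 sample without it at 0.976, while the samples with and without doxycycline correlated at 0.988 in the vector line, 0.987 in the wtAPE1 line and 0.971 in the ubAPE1 line. The highest correlation of any pair, 0.990, was between the wtAPE1 and ubAPE1 samples with doxycycline.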

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

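The 6 results here were picked because the response to doxycycline went opposite ways in a pair of cell lines, and none of these differences was tested, since each line has 1 averaged value per state. Mitosis genes lay above matched random lists in the wtAPE1 line and below them in the vector and ubAPE1 lines. Their median response was 0.35 log2 higher in the wtAPE1 than in the vector line, and the ubAPE1 line differed from the wtAPE1 line by -0.47. With the genomic length trend removed, which was chosen after seeing the data, the percentiles were 1.39, 99.9 and 0.06 in the vector, wtAPE1 and ubAPE1 lines. The wtAPE1 sample without doxycycline and the ubAPE1 sample with it correlated across rows at 0.988, against 0.971 for the ubAPE1 pair, and both had the lowest column median (6.07 log2). This likeness was not particular to them, since the wtAPE1 and ubAPE1 samples with doxycycline correlated at 0.990. A uniform offset of the columns cancels in these values, which are relative to the median row. A factor common to the wtAPE1 sample without doxycycline and the ubAPE1 sample with it was examined across rows below, without a decision. It was not tested for the mitosis genes. Before doxycycline, mitosis genes already lay low in the wtAPE1 line against the vector line, as given above, though inside the limits with the length trend removed. CHRM4, a muscarinic receptor gene, responded at least 1.5-fold down in the wtAPE1 line and up in both other lines, with differences of -1.93 from the vector line and 1.88 between ubAPE1 and wtAPE1. Without doxycycline, CHRM4 was already higher in the wtAPE1 than in the vector line, by 1.57 log2 relative to the median row. Both differences use that wtAPE1 sample. TOR1AIP2 differed by -1.87 between the ubAPE1 and vector lines on 1 row, and its other row gave -0.18 in the vector and -0.33 in the ubAPE1 line. GINM1 differed by -1.35 between the same lines. In all, 23 rows passed 1.5-fold in opposite directions, summed over the 3 pairs of lines.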

How the results depend on the processing

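Length removal and the left-out lines and other settings for camera were chosen after seeing the data, the other alternatives before. In all of these the cause of a change was not tested unless the setting itself gives it. Of the named gene values in tested comparisons, 518 stayed on their side of the threshold with their sign and 6 crossed to pass, all with centred columns. Of those in untested comparisons 535 moved by less than the median residual SD and 5 by more, all after quantile normalization, and none changed sign. Centring cannot change a value relative to the median row, so its 180 values here were bound to stay. The floor lies below the row filter, and all 180 values stayed with it too. The check of these values therefore rests on quantile normalization, where 175 stayed. Of the values of called list shifts under an alternative, 487 stayed outside the percentile limits with their sign, 59 kept their sign but came inside the limits, and 6 turned sign. The 487 include 69 with centred columns, which cannot move them, and 69 with the floor. Removing the length trend accounts for 22 of the 59, and 1 of the shifts that turned sign, among 69 called shifts.

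The 6 list shifts that turned sign were the neuronal markers without a row filter (0.14, 0.18, 0.15 and 0.11 log2 against random lists for wtAPE1 and ubAPE1 minus vector without doxycycline and over both states), the interferon-stimulated genes under the stricter filter (0.0569, ubAPE1 minus wtAPE1 over both states) and the histones with length removed (0.0405, ubAPE1 minus wtAPE1 without doxycycline). The filters add or remove list members.

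Counts of rows past the limma threshold moved as follows. For wtAPE1 minus vector the 245 rows became 112 with the stricter filter, 558 after quantile normalization and 656 with centred columns, and for ubAPE1 minus vector the 162 became 62, 434 and 539. Centring gave 9 rows for the common doxycycline effect and 1 for ubAPE1 minus wtAPE1, against 0. All other settings of limma gave 0 where the main setting did.

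By size, the vector, wtAPE1 and ubAPE1 responses had 123, 157 and 1039 rows past 1.5-fold. At 2-fold these were 5, 8 and 34. Without a filter the first pair became 275 and 303, the vector response 70 with the stricter filter, and the ubAPE1 response 506 (quantile) and 518 (centred). Differences in response for wtAPE1 minus vector (711 rows) became 1092 without a filter, 453 (quantile), 454 (centred) and 54 at 2-fold, for ubAPE1 minus vector (1689) 203 at 2-fold, and for ubAPE1 minus wtAPE1 (2465) 1376 (quantile), 1386 (centred) and 261 at 2-fold. Without doxycycline, wtAPE1 minus vector (1622) became 827, 828 and 280 in that order, ubAPE1 minus wtAPE1 (772) 244, 224 and 14, and ubAPE1 minus vector (497) 783 without a filter, 287 with the stricter filter and 120 at 2-fold. The 2-fold rule and the filters change which rows can count. The APEX1 response in the wtAPE1 line was 0.95 after quantile normalization, against 1.102.

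The 4 camera calls did not hold with an estimated correlation (adjusted p = 0.714 for the histones and the respiratory chain, 0.926 for glycolysis and the ATF4 targets). That version rests on the few residual degrees of freedom of the fit, so a list could hardly pass, and the loss does not decide on a call. As given above, the estimated correlation was over the preset for the histones, glycolysis and the ATF4 targets. Leaving out 1 cell line at a time with limma's camera gave adjusted p of 0.0616 to 0.181 for the ATF4 targets, 0.00161 to 0.0616 for glycolysis, 0.00161 to 0.315 for the respiratory chain and 4.92e-16 to 0.00874 for the histones. The glycolysis call was lost without the wtAPE1 line, and the respiratory chain call without the vector (0.173) or wtAPE1 line. Lists called only under another setting were the mitochondrial ribosomal proteins without a row filter (adjusted p = 0.0405) and the epithelial and mitosis lists without the wtAPE1 line (both adjusted p = 0.00504), and none of these held with an estimated correlation (adjusted p = 0.9008, 0.8015 and 0.8015).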

Other observations

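Of the tests here, the count after quantile normalization, the count with the length trend removed, the correlations of the ubAPE1 response with wtAPE1 minus vector, the correlations of line differences with the length trend removed, the percentile of the replication genes and the splits of the samples were chosen after the result was seen.

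The most extreme response by row count was the broad fall in the ubAPE1 line with doxycycline. The authors' scaling alone is argued against, since 372 rows were at least 1.5-fold lower after quantile normalization (all 372 also lower as deposited), against 63 in the vector line. The response followed genomic length with a Spearman rho of -0.41 across 9645 rows (0.15 in the vector and 0.22 in the wtAPE1 line). A length trend may therefore account for part of it. Genomic length includes introns and is not transcript length, so RNA integrity or priming as the source of the trend was not tested. A technical and a biological source were not told apart. Yet 229 rows were at least 1.5-fold lower with the trend removed, against 359 with it kept (173 shared) and 41 with it removed in the vector line. Olfactory receptor rows, taken as silent in these cells, spread 1.21 times as widely (95% bootstrap interval 0.981 to 1.49) in the ubAPE1 as in the vector line, which leaves a labelling or hybridization shift open. As deposited, their median ubAPE1 response was 0.145 log2 (95% bootstrap interval over rows 0.0633 to 0.204). The median kept row moved the other way, by -0.13. The uninduced wtAPE1 sample had a like fall and length trend against vector (rho -0.307). There, 1570 rows were lower as deposited, 597 relative to the median row and 571 after quantile normalization. With the length trend removed, the ubAPE1 response correlated with wtAPE1 minus vector at 0.365 without and 0.416 with doxycycline. The correlation was no higher without doxycycline, so it does not single out the uninduced wtAPE1 sample. Across rows, the ubAPE1 sample without doxycycline correlated with its own sample with doxycycline at 0.971. With the vector samples without and with doxycycline it correlated at 0.973 and 0.975, and with those of wtAPE1 at 0.976 and 0.985. These values leave open both an effect of the fusion and a factor common to the uninduced wtAPE1 sample and the ubAPE1 sample with doxycycline. They cannot tell which sample is the odd one. For APE1 itself, the wtAPE1 line had the larger APEX1 response (1.102 against 0.88 log2). That line had 34 rows lower and 123 higher as deposited, 49 and 59 relative to the median row.

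Both APE1 lines differed from the vector line in the same direction at most of the rows called. Chance values of the shared vector samples are argued against, because differences built from separate samples still correlated across rows at 0.487 and 0.711. A genomic length trend in both differences is argued against as the whole cause, since with the trend removed these correlations were 0.532 and 0.695. Uninduced APE1 acting before doxycycline stays open. Without doxycycline, APEX1 differed from the vector line as deposited by -0.04 log2 in the wtAPE1 and 0.29 in the ubAPE1 line. Relative to the median row these were 0.17 and 0.32. At the 157 rows called in both contrasts, induction moved levels further in the same direction by a median of 0.0521 log2. The 95% bootstrap interval (0.0129 to 0.102) is over rows of the same samples and does not measure how sure the induction effect is. Differences between separately derived lines, such as drift or selection, stay open and were not tested, since each line is a single derivative.

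Replication-dependent histones responded low in the vector and wtAPE1 lines. A smaller share of cells in S phase may be proposed and stays open. The DNA replication genes lay at percentile 77.9 in the wtAPE1 line and 19.1 in the vector line, inside the limits in both. These percentiles cannot decide, because the share of cells in S phase was not measured. Whether the replication list follows that share in these lines was not tested. An even shift of all short genes is argued against as the whole cause by lists of the 481 other genes in the shortest length class. Among these the histone median lay at percentile 0.01 in the vector line, 0 in the wtAPE1 line and 0.22 in the ubAPE1 line. The histone genes had a median genomic length of 494 bases, and the lists were drawn from the whole class. A trend that steepens toward the shortest genes within the class therefore stays open. An effect of doxycycline itself on histone transcripts, shared by lines with and without the transgene, stays open as a hypothesis. Camera's call for it did not hold with an estimated correlation, a version that could hardly pass with 2 residual degrees of freedom.

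For the common doxycycline effect, the 10 splits of the 6 samples into 3 and 3 are too few for a share under 0.05. The real split had 0 rows past the limma threshold and the others at most 0. With 0 rows in the real split, 10 of 10 splits give as many whatever the data, so the splits cannot decide.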
